A study of Danio rerio with 8 samples.

How the data were processed

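RNA-seq was done on zebrafish spinal cord from mstnb mutants and wild-type siblings, either uninjured or 1 week after complete transection (1 wpi). mstnb encodes one of the zebrafish myostatins, secreted TGF-beta family factors known as inhibitors of muscle growth. Per the labels, the tissue was a 2 mm section that included the lesion and some adjoining tissue, from fish of both sexes aged 3 to 9 months. Total RNA was made into TruSeq libraries and sequenced as 50 bp paired-end reads on an Illumina HiSeq instrument. The 8 libraries fall into 4 groups of 2 each: wild type uninjured, wild type 1 wpi, mutant uninjured and mutant 1 wpi. Groups were taken from the sample labels. One column name for the injured wild type carries the number 3, which no label has; that library was placed in its group by name and is called wild type 1 wpi 3 here. The labels do not say which animals, or how many, each library came from, so p-values measure only the spread between these libraries, which may in part be technical.

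The deposited data are 4 tables, each with the same 25309 entries by gene symbol and the same 8 columns of CPM (reads scaled to the library total), and each with one comparison by the authors. The CPM values deposited by the authors agreed between the tables to within a relative difference of 4.91e-10. In 1 of the tables, 16 symbols had been turned into dates; they were restored from the entries with the same CPM. Every CPM value was a whole multiple of what 1 read is worth in its library, within 0.01 reads, for 100% of the values, which gave back the reads per gene and the depth per library. Per the file headers, the authors' tables also hold baseMean, a mean of normalized read signal over the libraries, a log2 fold change with its standard error, a test score (the column stat) and p-values with adjusted p-values. These header names are those of DESeq2; the deposited score equals the log2 fold change over its standard error. Per the submitters' processing notes, Bowtie2, Cufflinks and Cuffdiff were used, without versions or roles. The genome build, the annotation, the counting program and its strand setting are not given in the sources used here. Reads of near-identical gene copies, such as the haemoglobin, zona pellucida, vitellogenin and muscle myosin families, and of overlapping or antisense genes, may therefore have been split or shared in an unknown way, so single members of these families are uncertain.

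The main test was limma 3.58.1 (R 4.3.3) with a trended prior variance on log2(CPM + 1), using the CPM as deposited. One model with 4 group means was fitted to all 8 libraries, which leaves 4 residual degrees of freedom, on the 19114 genes with a mean of at least 1 CPM in at least 1 group. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over the genes of that comparison. The pseudocount of 1 understates changes of genes with few reads. There were 6 comparisons: injury in wild type, injury in mutants, mutant against wild type in uninjured cord, the same at 1 wpi, injured mutant against uninjured wild type, and the interaction (the injury change in mutants minus that in wild type). Error terms after a log2 value are limma standard errors (SE), and those after a CPM value are standard deviations (SD). The design had been written for a table of counts, of CPM or of the authors' comparisons, and its part for CPM was followed. The tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined.

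Gene lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 25 lists. They cover the myostatin and activin pathway, neural progenitors and radial glia, neuronal differentiation, mature neurons, oligodendrocytes and myelin, macrophages and microglia, neutrophils, lymphocytes, fibroblasts and matrix, endothelium and pericytes, skeletal muscle, epidermis, erythrocytes, the cell cycle, FGF, Notch, Wnt, Hedgehog and BMP signalling, injury and regeneration-associated genes, the interferon response, cholesterol synthesis, oxidative phosphorylation, genes coded by the mitochondrial genome and the cytosolic ribosome. A further 2 lists, oocyte (37 genes) and liver (31 genes), were written after egg and yolk genes were seen among the largest changes, and were adjusted over 27 lists. In the group where its sum was lowest, 9 of the 37 oocyte genes still had a mean of 1 CPM or more, and so did 9 of the 31 liver genes; 0 genes of either are in another list. Across all lists, 8 genes were found under another symbol. A list member counts as changed if it passed over all genes tested, and counts adjusted over the list alone are given beside these.

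The mitochondrial share of a library was summed over 32 entries, those named mt- and 1 entry named after the mitochondrial genome record. Its 95% Wilson interval was at most ± 0.0173 percentage points, which covers counting error only. Replicates were compared before averaging: in all 4 groups they differed by far more than sampling noise, with a chi-square per degree of freedom of 16.7 or more, so none was treated as a repeat of another. TMM scaling factors (edgeR 4.0.16) moved the median log2 change of all tested genes by more than 0.1 for the comparisons across injury and for the interaction. For those 4 comparisons, log2 changes are given relative to the median of all genes. The p-values, adjusted p-values and calls of single genes test the unshifted log2 change against 0. They therefore do not test the relative change printed beside them.

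Alternatives fixed beforehand were: only the libraries of the compared groups, the replicate number as a block where the groups shared numbers, a change of at least 2-fold, a threshold of 0.01, a pseudocount of 0.1, no filter on low values, quantile normalization, each library left out in turn, other thresholds on the authors' tables, removal of muscle, erythrocyte and epidermis genes, and for lists a correlation estimated from the data or fry. Alternatives chosen after seeing the data were edgeR's quasi-likelihood test (TMM, 21772 genes) and DESeq2 1.42.0 on the recovered reads, TMM-scaled CPM, the oocyte score (the mean log2 value of the oocyte list) as a covariate, removal of oocyte and liver genes, and removal of the 2 libraries with the most oocyte transcripts. The oocyte list makes up the covariate, so its own test is not given with it. Members of the list also correlate with the score in part because they make it up. With group means in the model, the slope of the score rests on differences within groups. In each group replicate 1 had the higher score, so the slope may also stand for other differences between those libraries. Except for injured mutant against uninjured wild type, the score did not overlap between the groups compared. Results with the covariate in the other comparisons therefore rest on extrapolating the slope and cannot separate the score from the groups. The same holds for the interaction. For the 2 comparisons that share the uninjured wild type, unchanged groups were simulated 20 times from its means, its own libraries drawn with their own spread and the others with the spread pooled over groups. The settings planned for a table of counts alone (RLE and upper-quartile scaling, and every gene with at least 1 count) were set for another unit and not run, nor was Fisher's exact test, set for data with the authors' comparisons only. Before use, the test was checked on simulated counts drawn from these libraries with 50 genes changed at each size. The changed genes were drawn only from those with a mean CPM well above the filter. The rates below therefore do not hold for genes with few reads, for which recovery was not checked. For injury in wild type (18529 genes), limma found 6%, 70%, 100% and 100% of genes changed 2-, 4-, 8- and 16-fold, for mutant against wild type at 1 wpi (18592 genes) 4%, 68%, 94% and 100%, and for the interaction (18553 genes) 0%, 20%, 64% and 96%. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

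Named genes were chosen by a rule: per comparison, the 8 largest rises and the 8 largest falls among called genes whose libraries did not overlap between the groups, with a gene symbol that is not a clone name and at least 1 CPM in the higher group; from each list, up to 4 called members with the smallest adjusted p, or 2 with the smallest p where none was called; and in every comparison mstnb, mstna, gdf11, fgf1b, gfap, sox2, neurod1, hbaa1 and mylpfa. For the interaction, the injured or the uninjured libraries had not to overlap between genotypes. mstna was not analysed here, and gdf11 was under 1 CPM in every group and so was not tested. Genes named outside the rule are said to be so. Gene order on the chromosome came from a RefSeq gene table of assembly GRCz12tu, used only for names and for which genes neighbour each other. Left out were coordinates, because the build behind the deposited values is not given, and any analysis of the reads themselves, which were not used here.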

Results

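The data comprise 8 spinal cord libraries, 2 for each of wild type uninjured, wild type 1 wpi, mutant uninjured and mutant 1 wpi. Depth, as the total of reads behind the CPM values, was 22411820 and 24304589 for wild type uninjured 1 and 2, 20082743 and 20782901 for wild type 1 wpi 1 and 3, 33410514 and 25058706 for mutant uninjured 1 and 2, and 21895668 and 22697276 for mutant 1 wpi 1 and 2. In the shallowest library 1 read is worth 0.0498 CPM. Correlation of log2 values between the 2 libraries of a group, across genes, was 0.902 for wild type uninjured, 0.977 for wild type 1 wpi, 0.959 for mutant uninjured and 0.978 for mutant 1 wpi, so the uninjured replicates, above all those of the wild type, lay further apart than the injured ones. Their median absolute log2 difference was 0.586 in uninjured wild type and 0.524 in uninjured mutants. It was 0.258 in injured wild type and 0.240 in injured mutants. The model shares its variance over all 4 groups. Its SE may thus be too large between the injured groups and too small where uninjured groups are compared.

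Transcripts of tissues other than the cord differed widely between libraries. The summed CPM of the skeletal muscle list ranged from 2200 in wild type 1 wpi 1 to 32948 in wild type uninjured 1, with 9187 in wild type uninjured 2. Liver-list transcripts reached 7962 CPM in wild type uninjured 1 against 39.6 to 581 CPM in the other 7 libraries. Oocyte-list transcripts stood at 3399 CPM in mutant 1 wpi 1, 3005 in wild type uninjured 1, 959 in mutant 1 wpi 2 and 540 in wild type uninjured 2, against 35.9 and 36.3 CPM in the injured wild type. Mitochondrial reads made up 21.5% to 32.8% of the uninjured and 12.6% to 13.3% of the injured libraries.

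**Figure D1:**
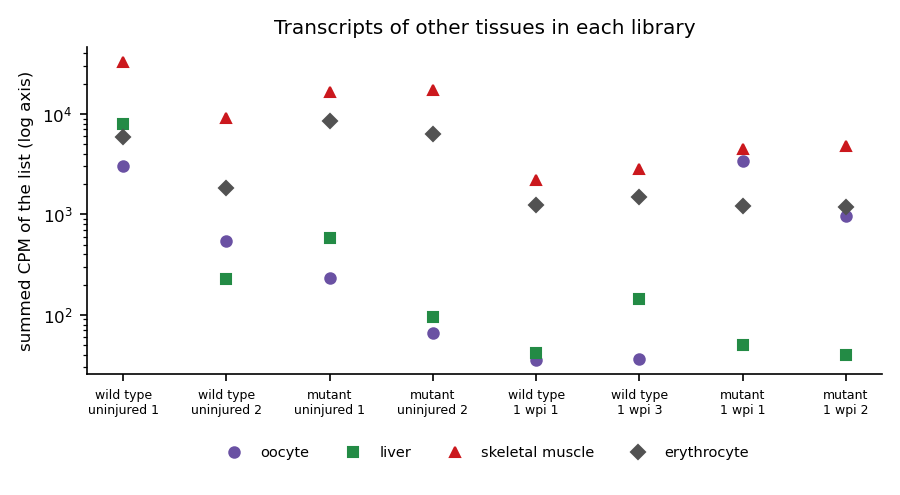
Summed CPM of the oocyte, liver, skeletal muscle and erythrocyte lists in each of the 8 libraries, on a logarithmic axis; each point is 1 library, placed by group. Oocyte transcripts are near 36 CPM in both injured wild-type libraries and at 959 and 3399 CPM in the injured mutant ones.

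The targeted gene was examined first. mstnb stood at 48.8 and 74.8 CPM in the uninjured and 45.2 and 42.2 CPM in the injured wild type, and at 10.2 and 26.4 CPM in the uninjured and 11.9 and 17.7 CPM in the injured mutants, so each mutant library lay below each wild-type one. Group means were 61.8 ± 18.4, 43.7 ± 2.13, 18.3 ± 11.4 and 14.8 ± 4.13 CPM (SD, n = 2 each). The mutant minus wild type difference was -1.81 ± 0.42 (log2 ± SE) in uninjured cord and -1.53 ± 0.42 at 1 wpi; neither passed in limma over all genes (adjusted p = 0.421 and 0.478). DESeq2 on the recovered reads gave adjusted p = 0.000961 and 0.00163. The authors' deposited table lists log2 changes of -1.79 and -1.64, with adjusted p of 7.62e-38 and 3.98e-29. Of the myostatin and activin pathway list, which also holds receptors, antagonists and SMAD factors, 0 of 31 members passed in either genotype comparison (list adjusted p = 0.929 and 0.924). Adjusted over the list alone, 1 was lower in uninjured mutants and 0 at 1 wpi.

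**Figure D2:**
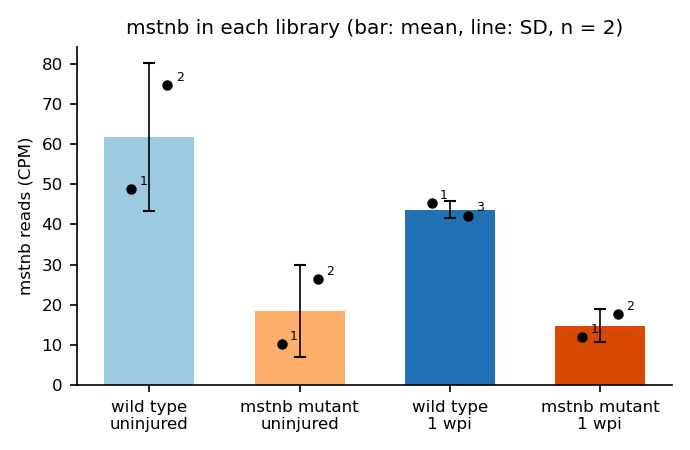
mstnb level in CPM in the 4 groups; bars are means of 2 libraries, error bars are SD and points are libraries with their replicate number. All 4 mutant libraries lie at or below 26.4 CPM and all 4 wild-type libraries at or above 42.2 CPM.

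Injured and uninjured wild-type cord were compared to find the response to transection 1 week later. TMM scaling moved the median change of all tested genes from 0.29 to 0.03, so changes are given relative to that median (log2 ± SE). Adjusted p-values and calls of single genes belong to the change before this shift. Of the lists, 15 of 46 injury-associated, 11 of 33 macrophage and 14 of 48 matrix genes rose. crlf1a, a secreted partner of ciliary neurotrophic factor-type cytokines, went from 1.41 ± 0.676 to 81.2 ± 26.7 CPM (SD, n = 2 each), a relative change of 4.79 ± 0.38. ndnf, a neurotrophic factor gene, rose from 9.67 ± 0.463 to 196 ± 11.7 CPM, mmp9, a matrix metalloproteinase, from 13.6 ± 9.68 to 211 ± 17.3 CPM, and apoeb, an apolipoprotein E gene strongly expressed by microglia, from 893 ± 188 to 16158 ± 1354 CPM. Falls were found for 20 of 46 skeletal muscle, 1 of 16 erythrocyte, 3 of 13 mitochondrially coded, 23 of 36 oocyte and 6 of 31 liver genes. These 5 lists were called lower, but with an estimated correlation their adjusted p were 0.344, 0.344, 0.344, 0.289 and 0.331, and those of the injury-associated, macrophage and matrix lists 0.391, 0.125 and 0.563.

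In limma, 737 of 19114 genes passed, 555 higher and 182 lower. With TMM-scaled CPM the split was 405 higher and 242 lower (62.6% against 75.3% higher), and 550 genes were called by both. edgeR called 461 genes (403 shared) and DESeq2 1649 (699 shared). The authors' deposited table lists 8907 genes at an adjusted p under 0.05, which include all 737. The other 4 of the 8 largest rises were tubb6, a beta-tubulin gene (4.36 ± 0.39), hapln1a, which codes for a hyaluronan link protein (4.30 ± 0.45), fkbp5, a glucocorticoid-responsive co-chaperone gene (3.97 ± 0.33), and the sodium channel gene scn4ab (3.94 ± 0.40). The adjusted p was 0.000227 for tubb6 and 9.55e-05 for crlf1a. The largest falls were those of the yolk precursor genes vtg1 (-8.43 ± 1.23, adjusted p = 0.00499), vtg2 and vtg5, of vtg4, which is listed at 0 in both injured wild-type libraries, of cldnd (-6.48) and of the egg coat genes zp3a.1 (-6.39 ± 0.98), zp3 (-6.29) and zp3f.1 (-5.84). The libraries behind these falls are uneven: the liver list, which holds yolk genes, reached 7962 CPM in 1 uninjured library and 229 CPM in the other.

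Among genes of neural cells, 5 of 32 progenitor and radial glia genes rose and 0 fell (6 and 1 adjusted over the list alone). They include the glial glutamate transporter slc1a3b (3.51 ± 0.43, from 0.928 ± 0.265 to 26.0 ± 6.36 CPM) and the intermediate filament genes nes and vim (1.01 ± 0.27). The list was called higher (adjusted p = 0.00911), but not with TMM scaling (adjusted p = 0.0771) and with adjusted p = 0.739 with an estimated correlation. Of 34 neuronal differentiation genes, 8 rose, adjusted over the list alone 9; those named are the growth cone gene gap43 (3.13 ± 0.37) and the tubulins tubb5 (3.75 ± 0.35, 101 ± 13.3 to 1669.9 ± 36.3 CPM) and tuba1b (2.38). The list itself did not pass (adjusted p = 0.0839). No mature neuron gene of 34 passed in limma, over all genes or adjusted over the list alone (list adjusted p = 0.173); vamp2, a synaptic vesicle gene, had the smallest p (1.14 ± 0.39, adjusted p = 0.0694). Myelin genes mag (1.46 ± 0.36) and cldn19 (1.15 ± 0.36) were the 2 of 17 oligodendrocyte genes that rose (5 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0839). The myelin gene mbpa of this list, named outside the rule, took up a smaller share of reads after injury. Its share was 7.87% and 8.08% in the uninjured and 3.74% and 3.69% in the injured wild-type libraries. In mutants it was 12.4% and 8.18% uninjured and 3.83% and 3.35% injured. gfap (0.26 ± 0.34), sox2 (0.25 ± 0.36), neurod1 (-0.81 ± 0.37) and fgf1b (0.24 ± 0.40), markers or regulators of radial glia and neurogenesis, did not pass, with adjusted p of 0.405, 0.441, 0.468 and 0.493, and neither did mstnb (-0.75 ± 0.42, adjusted p = 0.581).

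Of 33 macrophage and microglia genes 11 rose and 0 fell (17 and 0 adjusted over the list alone), among them the scavenger receptor gene marco (2.01 ± 0.34), the colony stimulating factor receptor gene csf1ra (1.97 ± 0.35) and havcr1 (1.68 ± 0.28). The list was called higher (adjusted p = 1.65e-08; adjusted p = 0.125 with an estimated correlation). Neutrophil genes mmp9 and mmp13b (1.84 ± 0.49), both metalloproteinases, rose of 13 tested (3 adjusted over the list alone). That list had a median of -0.04, a test direction of higher and adjusted p = 0.717. The lymphocyte list was called lower (median -0.58, adjusted p = 0.00911; adjusted p = 0.563 with an estimated correlation) with 0 of 21 members past the limma threshold, or past it adjusted over the list alone. Of 33 interferon response genes gbp1 (2.12 ± 0.51), gbp2 (1.52 ± 0.43) and the immunoproteasome gene psmb8a (1.45 ± 0.42) rose and the antiviral gene rsad2 fell (-3.30 ± 0.43). Adjusted over the list alone 5 rose and 1 fell, the median was -0.05 while the test pointed higher, and the list adjusted p was 0.318.

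Of the injury and regeneration-associated genes 15 of 46 rose and 0 fell (26 and 0 adjusted over the list alone). Besides crlf1a and mmp9, they include the annexin gene anxa2a (3.26 ± 0.38) and the stress-response transcription factor gene atf3 (2.46 ± 0.29). The list adjusted p was 3.32e-09, and adjusted p = 0.391 with an estimated correlation. Of the fibroblast and matrix genes 14 of 48 rose and 0 fell (25 higher and 1 lower adjusted over the list alone), led by the collagens col1a1a (3.28 ± 0.33, 6.14 ± 0.533 to 84.0 ± 14.6 CPM) and col1a2 (2.93 ± 0.33), the fibronectin gene fn1a (2.75 ± 0.33) and postnb (2.55 ± 0.37). The list had adjusted p = 3.90e-07, and adjusted p = 0.563 with an estimated correlation. Endothelial and pericyte genes pecam1 (1.93), rgs5b (1.47) and stab1 (1.40) were the 3 of 31 that rose, also adjusted over the list alone. The list median was 0.17, the test pointed lower and its adjusted p was 0.979. Cell cycle genes went both ways: mki67, a proliferation marker (1.78 ± 0.38), and tyms, a nucleotide synthesis gene (1.59 ± 0.44), rose, and ccnb2, a cyclin gene also expressed in oocytes, fell (-3.22 ± 0.66). Of 57 cell cycle genes 14 were higher and 4 lower adjusted over the list alone, and the list adjusted p was 0.741.

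Of the signalling lists none passed. Wnt members wnt4b (2.37 ± 0.35), ctnnb2 (1.51 ± 0.28), fzd2 (1.46 ± 0.32) and dkk1a (2.00 ± 0.42) were 4 of the 5 of 51 that rose (6 adjusted over the list alone, list adjusted p = 0.258). Notch members lfng (1.11) and dlb (1.83) rose of 32, also adjusted over the list alone (list adjusted p = 0.130). bambia, a decoy receptor gene of the TGF-beta family, rose (1.32 ± 0.32) as the 1 of 39 BMP members over all genes and adjusted over the list alone (list adjusted p = 0.496), and with fstb, a follistatin gene (1.64 ± 0.41), it makes up the 2 of 31 genes of the myostatin and activin pathway that rose (3 adjusted over the list alone, list adjusted p = 0.222). fgf20b fell (-1.86 ± 0.39) as the 1 of 33 FGF members (0 adjusted over the list alone, list adjusted p = 0.179). The 23 Hedgehog genes gave 0 in limma, also adjusted over the list alone, with gli2a nearest (1.12 ± 0.40, adjusted p = 0.0804; list median -0.02, test direction higher, adjusted p = 0.843).

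Skeletal muscle transcripts fell in 20 of 46 cases (3 higher and 27 lower adjusted over the list alone), including the parvalbumins pvalb3 (-4.69 ± 0.41) and pvalb4 (-4.00 ± 0.45), the actin gene actc1b (-3.50 ± 0.40), the creatine kinase gene ckmb (-2.40 ± 0.29) and the myosin light chain gene mylpfa (-4.16 ± 0.57). The list adjusted p was 6.47e-26, and adjusted p = 0.344 with an estimated correlation. hbaa1, an adult alpha-globin gene, fell (-1.93 ± 0.36, adjusted p = 0.0263) as the 1 of 16 erythrocyte genes, also adjusted over the list alone. The erythrocyte list median was -0.95 (adjusted p = 5.10e-07; adjusted p = 0.344 with an estimated correlation). All 13 mitochondrially coded genes had a list median of -1.26 (adjusted p = 3.08e-15; adjusted p = 0.344 with an estimated correlation). Of these genes 3 fell over all genes tested and 12 adjusted over the list alone, among them mt-nd3 (-1.84 ± 0.37) and mt-nd1 (-1.48 ± 0.26). Mitochondrial reads were 22.6% and 23.4% of the uninjured and 13.1% and 12.6% of the injured wild-type libraries. The nuclear oxidative phosphorylation list was also called lower (median -0.48, adjusted p = 1.62e-07; adjusted p = 0.563 with an estimated correlation). cox8b (-1.89 ± 0.29) was the 1 of 71 members to fall, also adjusted over the list alone. The cytosolic ribosome list was called higher (median 0.10, adjusted p = 0.00911; adjusted p = 0.908 with an estimated correlation, and 0.469 with TMM scaling) with 0 of 72 genes past the limma threshold or adjusted over the list alone. Cholesterol synthesis gave 0 of 26 in both counts (list adjusted p = 0.843), and the epidermis list gave 1 rise of 17, 3 adjusted over the list alone (list adjusted p = 0.137). Oocyte transcripts fell in 23 of 36 cases (30 adjusted over the list alone; median -3.73, adjusted p = 4.80e-43; adjusted p = 0.289 with an estimated correlation). Liver transcripts fell in 6 of 31 (13 adjusted over the list alone; median -2.81, adjusted p = 8.52e-25; adjusted p = 0.331 with an estimated correlation).

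Leaving out a library also removes the spread of its group from the shared variance. The count of genes for injury in wild type depended on single libraries. It was 70 without wild type 1 wpi 1, 57 without wild type 1 wpi 3 and 3834 without wild type uninjured 2, and 317 without the 2 libraries richest in oocyte transcripts (wild type uninjured 1 and mutant 1 wpi 1). Of the genes named above, psmb8a, tyms, ccnb2, mt-nd1 and mt-nd3 did not pass with TMM-scaled CPM. With the oocyte score as a covariate, oxidative phosphorylation was called higher instead of lower (adjusted p = 0.000858), as was the liver list (3.38e-10), and skeletal muscle (0.120) and erythrocytes (0.198, test direction higher) were no longer called. Lists called with it alone were the cell cycle (1.80e-14), neutrophils (0.0194) and epidermis (0.0394), higher, and mature neurons (2.34e-12) and FGF signalling (0.000858), lower. Of the 36 genes called with it, 25 were among the 737. On the raw log2 scale vtg4 (0.0397), vtg5 (0.70), ccnb2 (0.57) and mt-nd3 (0.0939) turned from lower to higher with it and did not pass. The libraries of the 2 groups alone gave 110 genes, all among the 737.

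**Figure D3:**
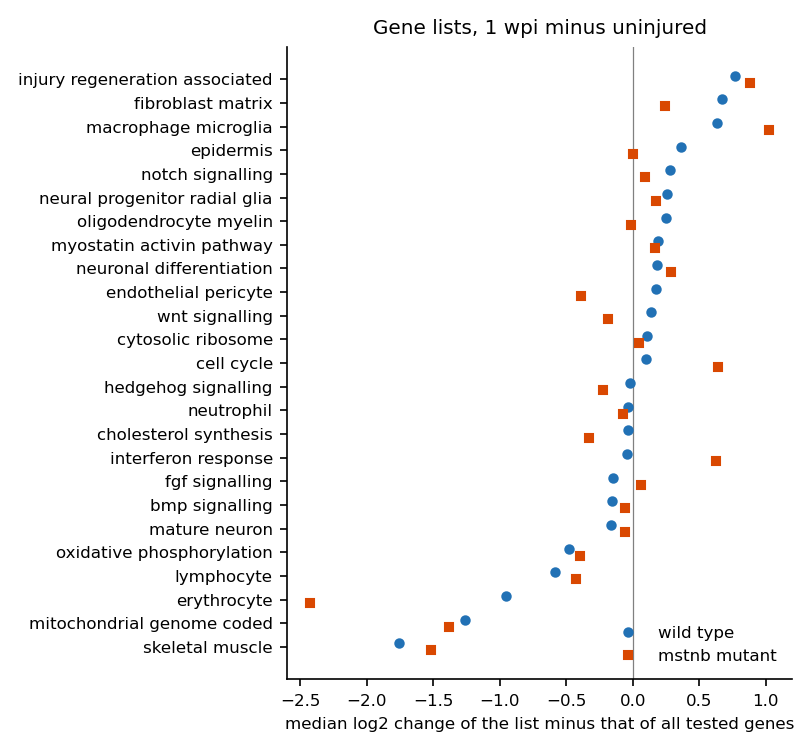
Median log2 change of each of the 25 gene lists from uninjured to 1 wpi, minus the median of all tested genes, for wild type and mutant. Macrophage and injury-associated lists lie above 0 and skeletal muscle, erythrocyte and mitochondrially coded lists below 0 in both genotypes, by medians such as 0.64 and 1.02 for macrophages in wild type and mutants.

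The same comparison in mutants asked how cord without normal mstnb responds to transection. TMM scaling moved the all-gene median from 0.37 to -0.01, and changes are again relative to it. ndnf (4.17 ± 0.28, 7.45 ± 0.296 to 195 ± 7.01 CPM, n = 2 each), scn4ab (4.29 ± 0.40), tubb6 (4.01 ± 0.39), crlf1a (3.99 ± 0.38) and apoeb (3.66 ± 0.30) rose here as well. Globin genes were among the largest falls: hbba2 went from 422 ± 263 to 9.89 ± 0.156 CPM (-5.49 ± 0.77) and hbaa1 from 1378 ± 85.3 to 180.4 ± 33.9 CPM (-3.31 ± 0.36). cyp19a1b, the brain aromatase gene known from radial glia, fell to 0.701 ± 0.494 CPM (-3.71 ± 0.48, adjusted p = 0.00415). In wild type cyp19a1b likewise went from 8.81 ± 4.95 to 0.265 ± 0.305 CPM. Egg genes such as zp3a.1 (4.72 ± 0.98), zp3f.1 (4.44 ± 0.91) and zar1l (4.12 ± 0.87) were among the largest rises, with oocyte-list sums of 3399 and 959 CPM in the injured against 235 and 65.2 CPM in the uninjured mutant libraries.

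In limma 610 genes passed, 562 higher and 48 lower; 55 of the higher ones had a correlation above 0.9 with the oocyte score over the 8 libraries. With TMM-scaled CPM 236 passed, 177 higher and 59 lower (562 and 48 without scaling), of which 214 were shared. edgeR called 144 and DESeq2 821; no table of the authors for this comparison was used here. The remaining named rises and falls were crp2 (4.90), zp3, hbaa2 (-4.86), hbba1 (-3.42), the erythrocyte anion exchanger gene slc4a1a (-3.30), the muscle actin gene acta1b (-3.90) and pvalb3 (-3.77).

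Macrophage and microglia genes rose in 15 of 33 cases (24 adjusted over the list alone), including lgals9l1 (1.94 ± 0.28), havcr1 (1.69 ± 0.28) and the invariant chain gene cd74a (1.47 ± 0.26). The list was called with both kinds of correlation (adjusted p = 7.39e-17; adjusted p = 0.0322 with an estimated correlation). Injury and regeneration-associated genes had adjusted p = 1.14e-12 as a list, and adjusted p = 0.222 with an estimated correlation. Of them 16 of 46 rose (30 adjusted over the list alone), with atf3 (3.01 ± 0.29), anxa2a (3.34 ± 0.38) and the cytokine signalling inhibitor gene socs3a (2.97 ± 0.37). Interferon response genes isg15 (2.80 ± 0.34, 2.80 ± 0.233 to 33.2 ± 2.75 CPM), gbp1 (1.87 ± 0.51) and gbp2 (1.97 ± 0.43) rose of 33 (16 higher and 1 lower adjusted over the list alone). The list adjusted p was 1.43e-05, and adjusted p = 0.222 with an estimated correlation. Cell cycle genes were called higher as a list (adjusted p = 1.30e-08; adjusted p = 0.311 with an estimated correlation). The members past the threshold were mcm2, a replication licensing gene (1.05 ± 0.33), kif23, a cytokinesis gene, and the cyclin gene ccnb1 (3.65 ± 0.86) of 57, 24 adjusted over the list alone.

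Neural progenitor genes slc1a3b (3.10 ± 0.43), foxj1a, a ciliogenesis factor gene (1.42 ± 0.29), nes (1.22 ± 0.32) and vim (0.87 ± 0.27) were the 4 of 32 that rose (8 adjusted over the list alone). The list adjusted p was 0.0226, 0.210 with TMM scaling, and adjusted p = 0.809 with an estimated correlation. The neuronal differentiation list was called higher (adjusted p = 0.00722; adjusted p = 0.884 with an estimated correlation). Of its members 4 of 34 rose, tubb5 (2.94 ± 0.35) and gap43 (2.57 ± 0.37) among them, and 8 adjusted over the list alone. gfap (0.05 ± 0.34), sox2 (0.40 ± 0.36), neurod1 (-0.61 ± 0.37), fgf1b and mstnb (-0.54 ± 0.42) did not pass. Fibroblast and matrix genes rose in 7 of 48 cases, 19 higher and 2 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.0982). Wnt members wnt4b (2.07), dkk1a (2.12), fzd2 (1.23) and rspo2 (1.59) were 4 of 5 that rose of 51, also 5 adjusted over the list alone (list adjusted p = 0.531).

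Erythrocyte genes fell in 10 of 16 cases (14 adjusted over the list alone; list adjusted p = 8.40e-37; adjusted p = 0.0340 with an estimated correlation). Skeletal muscle genes fell in 14 of 46 (1 higher and 21 lower adjusted over the list alone; list adjusted p = 1.08e-34; adjusted p = 0.173 with an estimated correlation), with mylpfa at -3.21 ± 0.57. Their summed CPM was 8454 and 6244 for erythrocytes and 16640 and 17347 for muscle in the uninjured libraries, against 1213 and 1184 and 4518 and 4779 in the injured ones. Also called lower were the mitochondrially coded list (adjusted p = 5.95e-24, 1 of 13 fell, 13 adjusted over the list alone), oxidative phosphorylation (adjusted p = 1.19e-05), lymphocytes (0.0135), endothelium and pericytes (0.0209, although 2 of 31 members rose) and cholesterol synthesis (0.0397). With an estimated correlation their adjusted p were 0.166, 0.698, 0.646, 0.718 and 0.884, and with TMM scaling the lymphocyte list did not pass (0.0793). Oocyte transcripts rose in 18 of 36 (adjusted p = 3.56e-15; adjusted p = 0.374 with an estimated correlation). The liver list was lower with 0 of 31 members past the limma threshold (adjusted p = 2.87e-17; adjusted p = 0.402 with an estimated correlation).

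The count was 58 without mutant 1 wpi 1, 78 without mutant 1 wpi 2 and 56 without mutant uninjured 1, and 336 without the 2 libraries richest in oocyte transcripts. Of the genes named for this comparison, crp2, zp3, zp3a.1, zp3f.1, zar1l, cd74a, gbp1, mcm2, kif23, ccnb1, foxj1a, nes, vim and mylpfa did not pass with TMM-scaled CPM. The oocyte score was 2.19 and 1.26 in uninjured and 5.02 and 3.63 in injured mutants, so calls with it as a covariate again rest on extrapolating the fit. The cell cycle list was called lower instead of higher with the oocyte score as a covariate (adjusted p = 0.0395). The neural progenitor (0.428, test direction lower), interferon response (0.192), lymphocyte (0.448) and endothelial (0.327) lists were not called with it. That fit called 3023 genes, 399 of them among the 610, and the libraries of the 2 groups alone gave 1234, which include all 610. Between genotypes, 323 genes were called higher after injury in both (16.3 expected for independent lists of these sizes) and 25 lower in both (0.457 expected), and 48 genes were called in opposite directions. The correlation of the wild-type and mutant injury changes across genes was 0.368, and genes are not independent replicates. No library is shared by these comparisons, but both use the same variance estimate per gene from 1 model. Their calls are therefore not independent, and the overlap expected for independent lists is not a full baseline.

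**Figure D4:**
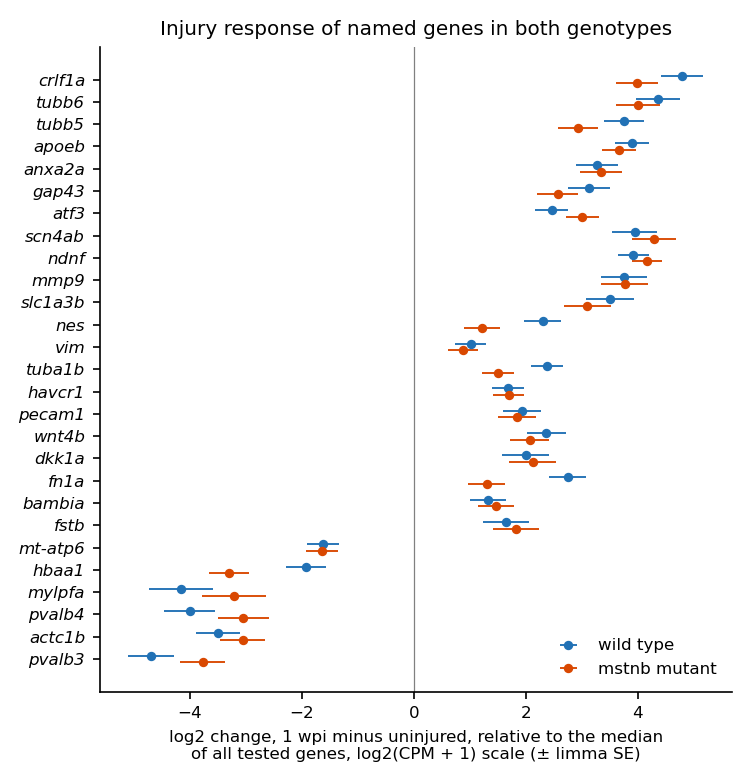
Log2 change from uninjured to 1 wpi relative to the median of all tested genes for 27 named genes, in wild type and mutant, on the log2(CPM + 1) scale; points are estimates and bars the limma SE. crlf1a, ndnf and apoeb lie far above 0 in both genotypes, at 4.79 and 3.99 for crlf1a.

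Mutant and wild-type cord were compared without injury to find effects of the mutation itself. No gene passed in limma: 0 of 19114 at an adjusted p under 0.05, against 852 at an unadjusted p under 0.05. The 852 are below a share of 0.05 of the tested genes, which would be expected if no gene differed. Fitted to the 4 libraries of these groups alone, limma called 93, 3 higher and 90 lower. Of the 25 lists, erythrocytes had the highest median difference (0.84 on the log2 scale), with summed CPM of 8454 and 6244 in mutants against 5869 and 1833 in wild type. Values of named genes include slc4a1a (1.67 ± 0.35, adjusted p = 0.409), alas2, a haem synthesis gene (1.85 ± 0.44, adjusted p = 0.421), col1a1a (1.77 ± 0.33, adjusted p = 0.401) and, lower in mutants, isg15 (-1.83 ± 0.34, adjusted p = 0.401). Neural genes gfap (0.15 ± 0.34), sox2 (-0.28 ± 0.36), neurod1 (-0.35 ± 0.37), fgf1b (0.12 ± 0.40) and nes (0.92 ± 0.32) did not pass either.

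limma on TMM-scaled CPM also called 0 genes, edgeR 0 (1266 of 21772 at an unadjusted p under 0.05, above a share of 0.05) and DESeq2 80, 24 higher and 56 lower. The authors' deposited table lists 5478 genes at an adjusted p under 0.05, 2345 higher and 3133 lower. Lists called higher in uninjured mutants were erythrocytes (adjusted p = 6.70e-12, 7 of 16 members adjusted over the list alone), skeletal muscle (0.00416), endothelium and pericytes (0.0235), fibroblasts and matrix (0.0291, 2 of 48 adjusted over the list alone), Wnt signalling (0.0291), cholesterol synthesis (0.0366) and oligodendrocytes (0.0389). Interferon response (0.000316, 1 of 33 lower adjusted over the list alone), oxidative phosphorylation (0.00123), macrophages (0.0190) and the cell cycle (0.0190) were called lower. With an estimated correlation the adjusted p was 0.507 for erythrocytes, 0.559 for interferon response, 0.559 for macrophages and 0.951 for the others, so no call held. With TMM scaling macrophages (0.0703), the cell cycle (0.0520) and oxidative phosphorylation (0.0520) also did not pass. With the oocyte score as a covariate, oxidative phosphorylation (adjusted p = 4.36e-07), the cell cycle (2.06e-08) and the liver list (3.51e-21) were called higher instead of lower. Macrophages (0.881), interferon response (0.173), endothelium (0.126), Wnt signalling (0.369) and oligodendrocytes (0.121) were no longer called with it. The oocyte and liver lists were lower in mutants (adjusted p = 6.28e-34 and 3.15e-12; adjusted p = 0.453 and 0.860 with an estimated correlation; 29 of 36 and 7 of 31 genes adjusted over the list alone). Oocyte-list sums were 3005 and 540 CPM in wild type against 235 and 65.2 in mutants. The count of genes was 825 without wild type uninjured 2, 4 without wild type uninjured 1, and 6 without the 2 libraries richest in oocyte transcripts.

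The comparison at 1 wpi asked whether mutant cord differs from wild type after injury. Egg genes led the called genes. zp3f.1 stood at 204 ± 157 CPM in mutants and 0.319 ± 0.0423 in wild type (SD, n = 2 each; log2 7.03 ± 0.91), and zp3a.1 at 223 ± 177 against 0.688 ± 0.224 CPM (log2 6.79 ± 0.98). slc40a1, which codes for ferroportin, the iron exporter, was the single lower gene, at 8.35 ± 0.961 against 45.8 ± 6.40 CPM (log2 -2.32 ± 0.34, adjusted p = 0.0164). Genes of radial glia and neurogenesis did not pass: gfap (0.02 ± 0.34), sox2 (-0.05 ± 0.36), neurod1 (-0.07 ± 0.37), neurod2 (0.89 ± 0.41) and fgf1b (-1.04 ± 0.40, 0.834 ± 0.370 against 2.75 ± 0.482 CPM, adjusted p = 1.00).

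In limma 51 genes passed, 50 higher and 1 lower; 47 had a correlation above 0.9 with the oocyte score over the 8 libraries. With TMM-scaled CPM 0 passed, as with quantile normalization and with edgeR (497 at an unadjusted p under 0.05), while DESeq2 called 145, 138 higher and 7 lower (48 shared). limma with unscaled CPM had 403 genes at an unadjusted p under 0.05. Both this count and the 497 of edgeR are below a share of 0.05 of the tested genes. The authors' deposited table lists 1457, 751 higher and 706 lower, which include all 51. Besides zp3f.1 and zp3a.1, the largest rises were cldnd (6.89), zp3 (6.69), crp2 (6.52), zar1l (6.03), zpax1 (5.64) and zp3e (5.45), with h1m and zp2.2 of the oocyte list at 5.29 and 5.66. Of 36 oocyte genes 17 rose (29 adjusted over the list alone; adjusted p = 6.48e-105; adjusted p = 0.137 with an estimated correlation), and oocyte-list sums were 3399 and 959 CPM in mutants against 35.9 and 36.3 in wild type. The liver list was lower (adjusted p = 0.0244; adjusted p = 0.986 with an estimated correlation, and 0.231 with TMM scaling). slc40a1 had adjusted p of 0.169 by edgeR and 2.38e-08 by DESeq2.

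Lists fixed beforehand that were called higher were skeletal muscle (median 0.60, adjusted p = 1.24e-09, 3 of 46 adjusted over the list alone) and the cell cycle (median 0.31, adjusted p = 8.12e-06, 3 of 57 adjusted over the list alone), the latter led by ccnb1 (4.35 ± 0.86, adjusted p = 0.0778), a cyclin gene abundant in eggs. Fibroblasts and matrix (median -0.28, adjusted p = 9.46e-09, 0 of 48 adjusted over the list alone) and erythrocytes (median -0.45, adjusted p = 1.53e-06, 2 of 16 adjusted over the list alone) were called lower. With an estimated correlation, adjusted p = 0.939 for each of these 4 lists, and 0 of their genes passed in limma over all genes. Skeletal muscle (adjusted p = 1.06e-07) and the cell cycle (1.10e-08) were called lower instead of higher with the oocyte score as a covariate. Examples are ampd1, a muscle enzyme gene (1.96 ± 0.40, adjusted p = 0.0890), col1a2 (-0.94 ± 0.33), postnb and hbaa2 (-3.23 ± 0.62, adjusted p = 0.0658). Summed muscle-list CPM was 4518 and 4779 in mutants and 2200 and 2824 in wild type, and erythrocyte-list CPM 1213 and 1184 against 1229 and 1477. The neural progenitor, neuronal differentiation, FGF and myostatin lists had adjusted p of 0.843, 0.843, 0.503 and 0.924. With the oocyte score as a covariate 10 of the 25 lists were called. Among them were neural progenitors, lower (0.00145), and neuronal differentiation (0.0201) and FGF signalling (0.0113), higher. At 1 wpi the score was 0.739 and 0.715 in wild type and 5.02 and 3.63 in mutants, so it nearly coincides with genotype there. These calls rest on extrapolating the fit and cannot separate the score from genotype. The count of 51 became 1 without wild type 1 wpi 1, 0 without wild type 1 wpi 3, 0 without mutant 1 wpi 1 and 82 without mutant 1 wpi 2; it was 69 (66 higher, 3 lower, 43 shared) without mutant 1 wpi 1 and wild type uninjured 1 together. The libraries of the 2 groups alone gave 231 genes (206 higher, 25 lower, all 51 included). With the oocyte score as a covariate 187 were called, 0 of which were among the 51; slc40a1 then had an adjusted p of 0.0738.

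Whether injury acted differently in the genotypes was tested directly by the interaction. TMM scaling moved the all-gene median from 0.09 to -0.03, and values are relative to it. Egg genes again led: zp3a.1 fell after injury in wild type and rose in mutants, a difference of 11.11 ± 1.38 (adjusted p = 0.00477), and crp2 (10.49), zp3 (10.38), zp3f.1 (10.27), cldnd (10.16), zpax1 (9.14), zar1l (9.13) and zp2l1 (8.95) followed. The collagen gene col1a1a was the single lower gene (-2.55 ± 0.46, adjusted p = 0.0374): it went from 6.14 ± 0.533 to 84.0 ± 14.6 CPM in wild type and from 23.6 ± 5.52 to 52.0 ± 12.8 CPM in mutants. Differences for gfap (-0.22 ± 0.48), sox2 (0.15 ± 0.51), neurod1 (0.19 ± 0.53), nes (-1.09 ± 0.46), fgf1b (-1.24 ± 0.57) and mstnb (0.20 ± 0.60) did not pass.

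In limma 108 genes passed, 107 higher and 1 lower, and 101 of the higher ones had a correlation above 0.9 with the oocyte score. The 108 include 24 members of the oocyte list, from which the score is made, so part of this correlation was built in. TMM-scaled CPM gave 34 genes (33 higher, 1 lower), quantile normalization and edgeR 0 (844 at an unadjusted p under 0.05 in edgeR, 619 in limma) and DESeq2 223. The 844 and the 619 are both below a share of 0.05 of the tested genes. Erythrocyte genes were called lower as a list (median -1.47, adjusted p = 1.89e-18; adjusted p = 0.240 with an estimated correlation; 4 of 16 adjusted over the list alone), as were fibroblasts and matrix (adjusted p = 2.11e-07), oligodendrocytes (0.0111), epidermis (0.0274, 0.0661 with TMM scaling) and endothelium (0.0368). The cell cycle (8.87e-06) and interferon response (0.000451) were called higher. With an estimated correlation the adjusted p was 0.621 for fibroblasts, oligodendrocytes, epidermis, the cell cycle and interferon response, and 0.918 for endothelium. ccnb1 (7.25 ± 1.21) and ccnb2 (5.06 ± 0.93) were the 2 cell cycle members that passed of 57, and isg15 (1.78 ± 0.48, adjusted p = 0.253) did not. Neither cyclin gene passed with TMM-scaled CPM. On the raw log2 scale they turned lower with the oocyte score as a covariate, to -1.73 and -1.08, and did not pass. That fit called 15 genes, 0 of which were among the 108. As the score did not overlap between genotypes in either injury state, results with it as a covariate rest on extrapolating the fit. With the oocyte score as a covariate, the cell cycle (adjusted p = 1.13e-09) and the liver list (2.22e-49) were called lower instead of higher. Interferon response (1.00), oligodendrocytes (0.385), epidermis (0.0701) and endothelium (0.524) were not called with it. Of 36 oocyte genes 24 passed (adjusted p = 6.03e-92; adjusted p = 0.130 with an estimated correlation); the liver list was called higher (adjusted p = 6.00e-05; adjusted p = 0.969 with an estimated correlation). Without the 2 libraries richest in oocyte transcripts the adjusted p of col1a1a was 0.239, and over TMM scaling, edgeR, DESeq2 and the oocyte covariate it lay between 2.94e-06 and 0.423. The count was 54 and 59 without wild type 1 wpi 1 and 3, 52 without mutant 1 wpi 1, 350 without wild type uninjured 2, and 33 and 0 without mutant uninjured 1 and 2.

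The authors also set injured mutants against uninjured wild type, which mixes injury and genotype. TMM scaling moved the all-gene median from 0.32 to 0.04. The genes that rose were largely those of injury in wild type: crlf1a (4.62 ± 0.38), fkbp5 (4.12 ± 0.33), scn4ab (4.08 ± 0.40), hapln1a (4.01 ± 0.45), tubb6 (4.01), ndnf (3.87), prg4a, a lubricin gene (3.80), and apoeb (3.64). Yolk genes vtg1 (-8.66 ± 1.23), vtg2 (-7.31), vtg5 (-6.60), vtg4 (-6.46) and vtg6 (-5.79), the globins hbaa2 (-5.10) and hbba2 (-4.77) and pvalb3 (-4.01) fell furthest. mstnb fell (-2.31 ± 0.42, adjusted p = 0.0325). vtg4, vtg5 and vtg6 did not pass with TMM-scaled CPM.

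limma called 479 genes, 423 higher and 56 lower (88.3% higher), TMM-scaled CPM 363, 270 higher and 93 lower (74.4%), edgeR 197 and DESeq2 1279; the authors' deposited table lists 8378. Macrophage (9 of 33 rose, 19 adjusted over the list alone; adjusted p = 3.22e-10), injury and regeneration-associated (11 of 46, 24 adjusted over the list alone; 4.98e-09), cell cycle (0.00248), fibroblast (10 of 48; 0.00414) and neural progenitor lists (3 of 32; 0.00777) were called higher. Skeletal muscle (8 of 46 fell; 1.57e-18), erythrocytes (4 of 16; 1.93e-14), oxidative phosphorylation (7.12e-11), mitochondrially coded genes (1.47e-15) and lymphocytes (0.0187) were called lower. With an estimated correlation the adjusted p ranged from 0.0887 for macrophages to 0.881 for fibroblasts, so no call held, and with TMM scaling the neural progenitor (0.0966) and lymphocyte (0.101) lists did not pass. The cell cycle (0.0812) and lymphocyte (0.0639) lists did not pass with the oocyte score as a covariate. The oocyte list median was 0.05 while its test pointed lower (adjusted p = 0.247); the liver list was called lower (adjusted p = 1.16e-34; adjusted p = 0.360 with an estimated correlation). Both this comparison and injury in wild type use the uninjured wild type. They shared 360 genes called higher (12.3 expected for independent lists) and 41 called lower (0.533 expected), with a correlation of changes across genes of 0.791 against 0.654 simulated for unchanged groups sharing those controls, and a covariance of 0.418 against 0.212, a difference of 0.207. With 1 of the 2 control libraries used for each comparison, so that none was shared, the correlation was 0.258 and 0.365 for the 2 ways to divide them, and the mean covariance 0.212. Part of the correlation may therefore come from the shared controls. The simulation cannot show what shared controls add to the overlap, because almost no gene was called in either simulated comparison. Its means were 0 higher and 0 lower for injury in wild type, and 0 higher and 0.05 lower for the other. Both comparisons also use the same variance estimate per gene. Whether shared controls add to the overlap of changed genes was not tested. The count of 479 became 36 without mutant 1 wpi 1, 18 without mutant 1 wpi 2, 3629 without wild type uninjured 2 and 93 without the 2 libraries richest in oocyte transcripts. It was 7, all among the 479, with the libraries of the 2 groups alone, and 2934, which include all 479, with the oocyte score as a covariate.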

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

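The test of oocyte RNA and the test of loss of mstnb in this part, and the fits without the 2 libraries richest in oocyte transcripts, were chosen only after the result was seen.

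The interaction of genotype and injury called 107 genes higher and 1 lower in limma: their injury change differed between mutants and wild type. The largest raw log2 differences were 11.20 for zp3a.1, 10.57 for crp2, 10.47 for zp3, 10.35 for zp3f.1, 10.24 for cldnd, 9.22 for zpax1, 9.22 for zar1l and 9.03 for zp2l1. All of them correlated above 0.9 with the oocyte score over the 8 libraries. The score is made from the oocyte list, which holds zp3a.1 and was written after such genes were seen. It also fell after injury in wild type and rose in mutants, the pattern for which these genes were picked. Part of the correlation follows from these choices. col1a1a was lower by this test, at -2.46. Among the lists, the interaction had adjusted p of 1.89e-18 for erythrocytes, 2.11e-07 for fibroblasts and matrix, 8.87e-06 for the cell cycle, 0.000451 for interferon response, 0.0111 for oligodendrocytes, 0.0274 for epidermis and 0.0368 for endothelium and pericytes. These 7 lists had adjusted p between 0.240 and 0.918 with an estimated correlation, so none was called, and fry called 0. With the oocyte score as a covariate the cell cycle list turned lower (adjusted p = 1.13e-09).

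The genes called between mutant and wild type at 1 wpi were weighed as the first pattern. A candidate explanation is RNA of oocytes in some libraries: 92.2% of the 51 called genes correlated above 0.9 with the oocyte score over the 8 libraries, and 30 of the 34 that are not in the oocyte list (88.2%) did so, against 192 of 19114 (1.00%) of all tested genes. The score itself separates the genotypes at 1 wpi, the contrast for which these genes were picked. Part of the correlation therefore follows from that choice, and the share of all tested genes is not a like comparison. The most abundant oocyte-list genes in injured mutants, zp3.2 and zp3a.1, stood at 513 and 142 CPM and at 348 and 98.4 CPM there, against 4.08 and 3.13 CPM and 0.846 and 0.529 CPM in injured wild type. If loss of mstnb raised these genes whatever the injury state, they would be higher in uninjured mutants too. Their median mutant minus wild type difference in uninjured cord was instead -3.16 on the log2 scale (quartiles -3.67 and -2.43). Of the 50 higher genes, 48 lay below 0. That goes against this explanation but does not exclude it, as most of these genes follow the oocyte score. Oocyte-list sums were 3005 and 540 CPM in uninjured wild type against 235 and 65.2 in uninjured mutants. Such a difference could hide an effect of the mutation. An effect of the mutation only after injury, and differences in sex or in ovarian tissue between the fish of each library, which the labels do not give per library, stay open.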

How the results depend on the processing

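The fits by edgeR and DESeq2, TMM scaling, the oocyte score as covariate, the removal of the 2 libraries richest in oocyte transcripts and the 6-library fits without the block were chosen after the data were seen; all others were fixed beforehand.

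Counts of called genes are given in the order injury in wild type, mutant against wild type uninjured, the same at 1 wpi, injured mutant against uninjured wild type, injury in mutants and the interaction, for which the values were 737, 0, 51, 479, 610 and 108. With only the libraries of the compared groups the first 5 became 110, 93, 231, 7 and 1234. At a threshold of 0.01 they were 193, 0, 0, 101, 122 and 47. A pseudocount of 0.1 moved the third to 79, and no filter on low values moved the third to the sixth to 17, 299, 382 and 63. Quantile normalization gave 0 for the third, 320 for injury in mutants and 0 for the interaction. TMM scaling gave 0, 236 and 34 for the same 3. edgeR gave 461, 0, 0, 197, 144 and 0, and DESeq2 1649, 80, 145, 1279, 821 and 223. The oocyte covariate gave 36, 4, 187, 2934, 3023 and 15, of which 25, 0, 0, 479, 399 and 0 were among the genes called without it. Without the 2 libraries richest in oocyte transcripts the counts were 317, 6, 69, 93 and 336 for the first 5. Leaving out 1 library at a time, where the lone library of a group is assumed to vary like the others, gave 57 to 3834, 0 to 825, 0 to 82, 18 to 3629, 56 to 472 and 0 to 350. Removal of muscle, erythrocyte and epidermis genes, or of oocyte and liver genes, and a 2-fold minimum kept every count within 1.5 times of its value. Without oocyte and liver genes the count for mutant against wild type at 1 wpi was 34 rather than 51. List genes were only dropped from the finished calls, without a new fit, and every called gene had already changed at least 2-fold. These settings therefore cannot show how far RNA of other tissues affects the counts.

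Lists called were 10, 11, 4, 10, 13 and 7. With an estimated correlation they were 0, 0, 0, 0, 2 and 0, and with fry 1, 0, 0, 1, 6 and 0. The oocyte covariate gave 10 for mutant against wild type at 1 wpi and 12 for the interaction. In the authors' tables a 2-fold minimum left 3989, 1866, 578 and 3543 genes for the first 4 comparisons, and an adjusted p under 0.01 left 3489 (uninjured) and 840 (1 wpi). Under the oocyte covariate 7 named genes reversed: vtg4 (0.0397), vtg5 (0.70), ccnb2 (0.57) and mt-nd3 (0.0939) for injury in wild type, epcam (-3.48) for mutant against wild type at 1 wpi, and ccnb1 (-1.73) and ccnb2 (-1.08) for the interaction. With quantile normalization 7 list calls ended: liver (adjusted p = 0.225) for mutant against wild type at 1 wpi, oxidative phosphorylation (0.471) and Wnt signalling (0.0555) for mutant against wild type uninjured, neural progenitors (0.0983) and lymphocytes (0.0931) for injury in mutants, and epidermis (0.0768) and endothelium (0.0561) for the interaction. The cause of the changes in this part was not tested.

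Replicate numbers 1 and 2 recur in 3 groups, and the labels do not say what else libraries of the same number share. Residuals of same-numbered libraries correlated at 0.299, 0.213 and 0.199, over 2 pairs each, which is too few to tell whether they belong together. With the replicate block on the 6 libraries other than wild type 1 wpi, 179, 1547 and 1391 genes were called for mutant against wild type uninjured, injured mutant against uninjured wild type and injury in mutants, against 0, 157 and 246 on those libraries without it. Called lists under the block were 11, 11 and 12. No paired analysis was possible for comparisons with wild type 1 wpi because a column of that group carries a number that no label gives. RLE and upper-quartile scaling, the filter of at least 1 count and Fisher's exact test on lists were not run, as they had been set for other units. With 2 libraries per group, simulated 2-fold changes were found in 0% to 6% of cases, so changes of that size are mostly out of reach.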

Other observations

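The contrast of both mutant groups against both wild-type groups, the shares by chromosome and the comparison with DESeq2's default fit were chosen only after the result was seen, and so were the genes si:dkey-18p12.4, zgc:113314, myha, tfpia, ralba, cyp27a1.2 and abca12.

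Averaged over injury states, 4 genes differed between genotypes in limma. si:dkey-18p12.4 (2.98 on the log2 scale, adjusted p = 0.0160), zgc:113314 (2.14, adjusted p = 0.0246) and the myosin heavy chain gene myha (2.86, adjusted p = 0.0279) were higher in mutants, each in 4 of 4 mutant libraries above 4 of 4 wild-type libraries. slc40a1 was lower (-2.05, adjusted p = 0.0172), at 7.57 to 9.82 CPM in mutants and 27.3 to 50.3 CPM in wild type. By gene order in assembly GRCz12tu, 3 of the 4 lie on the chromosome of mstnb: zgc:113314 and si:dkey-18p12.4 at positions -157 and -158 and slc40a1 at position 7, counted in genes from mstnb; myha is placed on another chromosome.

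Genes on the chromosome of mstnb were then counted at an unadjusted limma p under 0.01 for the genotype average. Of the 100 tested genes nearest mstnb 5 (5%) had such a p, against 59 of 16464 others (0.358%), a ratio of 14.0; without slc40a1 the share was 4.04%. The others include the rest of that chromosome, where 17 of 511 genes (3.33%) had such a p, against 42 of 15953 (0.263%) on other chromosomes. The difference between the 100 nearest and the rest of the chromosome was not tested. The 5 near genes were slc40a1, tfpia, ralba and abca12, lower in mutants, and cyp27a1.2, higher; of these only slc40a1 passed after adjustment. Alleles linked to the mutated locus and inherited with it may account for this ratio, as may an effect of the mutation on its neighbours, which was not tested. A limma model with genotype and injury state as additive terms, which can be fitted to other splits too, gave 8 such genes among the 100. Of the 18 splits of the 8 libraries with 2 of 4 on each side in each injury state, 1 (the real one) gave as many under that model, 8 against at most 6 in the others; the splits are too few for a share under 0.05 (the smallest is 0.0556).

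The authors' standard errors were smaller than those of a default fit. DESeq2 on the recovered reads gave standard errors a median of 1.94 times the deposited ones (quartiles 1.60 and 2.49). These figures cover 79160 values with a baseMean of 10 or more. Only the fit run here is thereby excluded as their source. Default fits to other sets of these libraries, or with other DESeq2 versions, were not run. The version behind the deposited errors is not given in the sources used here, so such fits are not excluded. With each gene's replicates set to their geometric mean, and gene-wise dispersions because the trend could not be fitted, the ratio was 0.459 (quartiles 0.413 and 0.502). A complete removal of replicate differences did not give the deposited errors in that fit. Without the dispersion trend, however, the fit cannot exclude it. How the deposited errors were made stays open, and no biological explanation was tested.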
